A study of Homo sapiens with 36 samples.

How the data were processed

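Skin biopsies from people with necrobiosis lipoidica, a granulomatous disease of the dermis, were taken in an open-label study of topical ruxolitinib, an inhibitor of the Janus kinases JAK1 and JAK2. RNA was isolated with the miRNeasy Mini Kit and 40 ng of total RNA per biopsy went into exome-capture sequencing libraries (RNA Access), per the labels' protocols. Capture probes enrich coding exons, so noncoding and mitochondrial transcripts are measured less completely than coding ones. The labels gave 3 groups of 12 libraries: nonlesional skin at week 0, lesional skin at week 0 and treated lesional skin at week 4.

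Per the submitters' processing notes, the tools were bcl2fastq 2.19.0, STAR 2.6.1c and the Subread program featureCounts, with the genome build hg38. Settings, strand handling and the annotation release are not given in the sources used here. The deposited table gave 2 values per gene and library. The authors' counts per gene were whole numbers with no normalization, per the file headers and the values. The authors' FPKM equalled the count divided by the gene length in the file and by the total count of that library, per the file headers and a recomputation in which the ratio of the 2 denominators was 1 in every library. The gene length is a deposited column of the authors in bp, and it entered no test other than through the FPKM. Gene symbols, identifiers and coordinates are those of the authors' file.

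The labels mark 3 libraries as left out of the authors' differential analysis, 1 of nonlesional and 2 of lesional skin, and the tests here left them out too. That left 11 nonlesional, 10 lesional and 12 treated lesional libraries. The file has 64253 gene entries. XIST, TSIX and genes of the Y chromosome (617 entries) were removed before any step. In 246 of the tested entries the symbol belongs to more than 1 tested entry. Genes were kept where edgeR's filterByExpr found enough counts for the groups, which left 18589 genes, 15610 of them protein coding. No 2 libraries had identical counts, and the highest Pearson r between 2 libraries of a group was 0.963 on the log2 CPM scale.

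Total counts per library ran from 14.6 to 67.9 M (M for 1e6) with a median of 33.2 M over the 36 libraries. The median standard error of a log2 fold change was 0.27 for lesional against nonlesional skin, 0.26 for week 4 against week 0 and 0.25 for treated lesional against nonlesional skin. Reads carry no molecular identifiers in the sources used here, so a count is not a count of independent molecules.

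Fold changes and p-values came from edgeR 4.0.16 in R 4.3.3: TMM scaling, a quasi-likelihood fit with robust dispersion over the 3 groups, and an F test for each of 3 comparisons, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. An adjusted p given for a gene comes from that edgeR test unless another tool is named. CPM are counts per 1e6 counts with TMM scaling. Errors of CPM are SD over biopsies, and errors of log2 fold changes are standard errors. "Rose" and "fell" describe genes and lists that passed their test. The labels tie no biopsy to a patient, so each p-value treats the biopsies as independent. If biopsies of a patient resemble each other, the p-values are not exact, and changes within patients, such as those at week 4, can be missed. The series' design text counts 8 responsive lesions and 4 refractory ones at week 4. The labels do not tell which is which, so these were not compared and the week 4 group is a mixture.

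There were 34 gene lists for skin, immune and stromal cell types and pathways. The lists, tests and named-gene rule were fixed before the data were examined. Each list had 3 readouts. Its members were counted by edgeR call, adjusted over all genes and adjusted over the list alone. A score per biopsy, the mean of its members' z-scored log2 CPM (prior count 2), was compared by a two-sided permutation test with 100000 resamples, adjusted over the 102 tests of lists and comparisons. The smallest p these resamples can give is 1e-05. The gene set tests camera (preset correlation between genes of 0.01, or an estimated one) and fry from limma 3.58.1 were run on log2 CPM. Their p-values were also adjusted over the 102 tests of lists and comparisons. Camera compares a list with other genes. Fry tests whether a list's genes move one way and does not compare them with other genes. Lists share members, among them CTSS in 3 lists.

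Genes were named by this rule: in each of the first 2 comparisons, the 10 largest rises and falls among genes with an adjusted p under 0.05, at least a 2-fold change, an average log2 CPM of at least 1 and at least 80% of biopsies of a group beyond the median of the other, and 5 in each direction in the third comparison. From each list the 4 members with the smallest p in each of the first 2 comparisons could be named, whether they passed or not, and JAK1, JAK2, JAK3, TYK2, STAT2, STAT3, STAT4, STAT5A, STAT5B and STAT6 always. Some results for genes that these rules named are not reported here. Genes whose presence depends on genotype, variable antibody and T cell receptor segments, and pseudogenes were never named. Immunoglobulin constant genes, alpha globins and keratin and S100 families have near-identical copies. How the authors' counting split reads among copies is not stated, so values of single members are uncertain.

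The share of the lesional change reversed at week 4 was the median over genes, changed at least 2-fold in lesional skin, of minus the week 4 change divided by the lesional change. Lesional libraries were halved at random, with genes and lesional changes taken from one part and week 4 changes from the other, over 20 halvings.

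The gene test was tested on simulated counts drawn from the real means and library sizes for the 18589 genes, in 5 runs per comparison with 250 changed genes per fold size in all. Changed genes were drawn only from those with an average log2 CPM above 1, so the shares do not hold for weaker genes. For lesional against nonlesional skin, 21.2%, 59.6%, 93.6% and 97.6% of genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered, and 18 of 90610 unchanged genes were called. For week 4 against week 0 in lesional skin the shares were 26.4%, 61.2%, 93.2% and 98.0%, with 30 of 90632 unchanged genes called. For treated lesional against nonlesional skin they were 20.0%, 61.2%, 92.0% and 98.4%, with 22 of 90412 called. In each comparison the cell cycle list, shifted 1.5-fold, was called in 5 of 5 runs and 0 of 165 tests of other lists were. Few genes were changed in each run, while 8649 and 7480 passed in the real comparisons of lesional and treated lesional with nonlesional skin. With so many changes the adjusted threshold falls at a larger unadjusted p, so the recovered shares do not describe those comparisons. Simulated genes were independent, which real members of a list are not. All biopsies of a simulated group changed alike, so the week 4 shares do not apply to a mixture of responsive and refractory lesions.

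Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter on low counts, a filter of 50 counts in 10 libraries, all 36 libraries, a fit to the groups compared alone, log10 total count as a covariate, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), a 2-fold minimum, and for lists the median member. Tests without 3 low-complexity libraries (fewer than 500 genes at exactly 1 count), with protein-coding genes alone, and with list scores adjusted within a comparison were chosen after seeing the data. Figures were drawn with matplotlib.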

Results

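RNA was measured in skin biopsies of necrobiosis lipoidica, in which inflamed granulomas surround degraded collagen. The comparisons covered nonlesional skin at week 0 (n = 11), lesional skin at week 0 (n = 10) and lesional skin at week 4 of topical ruxolitinib (n = 12). Total counts per library were 27.4 ± 11.6 M in nonlesional, 41.3 ± 12.4 M in lesional and 34.1 ± 10.3 M in treated lesional skin (mean ± SD, M for 1e6). On the first 2 principal components, which held 55.5% and 7.08% of the variance of 2000 genes, nonlesional libraries lay at -114 to -67 on the first, lesional ones at 7.06 to 96.7 and treated lesional ones at -30.3 to 111.

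**Figure D1:**
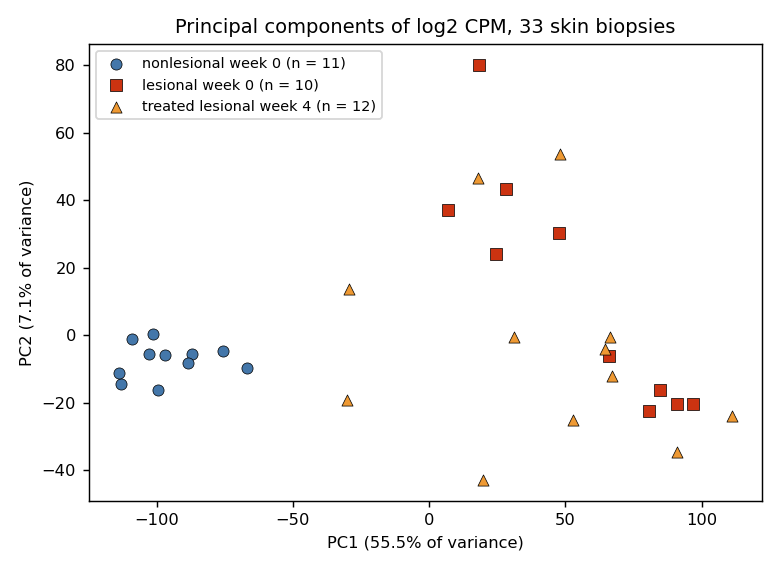
Principal components 1 and 2 of log2 CPM, with 1 point per biopsy and marker and colour for the group. Component 1 holds 55.5% of the variance, and 10 of 12 treated lesional biopsies lie in or beyond the lesional range, while 2 lie between the lesional and the nonlesional biopsies.

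The first comparison asked how lesional skin differed from nonlesional skin before therapy. CHIT1, the chitinase of activated macrophages (ENSG00000133063, chromosome 1, 203212827 to 203273641 on hg38), was at 1.03 ± 2.76 CPM in nonlesional and 1072 ± 1003 CPM in lesional skin, a log2 fold change of 10.06 ± 1.40 (adjusted p = 8.72e-07). SPP1, the secreted phosphoprotein osteopontin, rose from 3.43 ± 5.75 to 2725 ± 1769 CPM (9.65 ± 1.21, adjusted p = 1.41e-07). MMP1, the interstitial collagenase (ENSG00000196611, chromosome 11, 102789920 to 102798160), rose from 0.0705 ± 0.161 to 138 ± 305 CPM (10.77 ± 1.45, adjusted p = 4.93e-07). WIF1, a secreted inhibitor of Wnt signalling (ENSG00000156076, chromosome 12, 65050626 to 65121566), fell from 14.4 ± 12.3 to 0.185 ± 0.299 CPM (-6.29 ± 0.90, adjusted p = 1.09e-06). Each of the 4 lay beyond the nonlesional median in 10 of 10 lesional biopsies. In all, 8649 of 18589 genes changed, 4446 upward and 4203 downward, and 2706 and 2179 of them changed at least 2-fold. Falls outnumbered rises under 7 alternatives, among them DESeq2 size factors (4280 upward and 4406 downward), upper-quartile scaling (3996 and 4765) and limma-trend on log2(FPKM + 1) (3829 and 4463).

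Other large rises included antibody and chemokine genes. IGHM, the constant region of IgM, rose by 11.52 ± 1.80 on the log2 scale. IGHG1, IGHG2 and IGHG3, constant regions of IgG, rose by 10.43 ± 1.44, 9.28 ± 1.52 and 9.51 ± 1.61, with levels as shared among near-identical copies. CXCL8, a chemoattractant of neutrophils, rose from 0.0235 ± 0.0453 to 15.8 ± 8.79 CPM (9.36 ± 0.98). IGLC7 (0.0122 ± 0.0404 to 47.3 ± 69.3 CPM) and OLR1, a receptor for oxidised lipoprotein (0.00904 ± 0.0207 to 25.4 ± 19.0 CPM), also rose, and no fold is given because their nonlesional counts summed to 3 or fewer. Immunoglobulin genes took 0.0106 ± 0.00709% of counts in nonlesional and 5.08 ± 5.52% in lesional biopsies, and the share was over 1% in 0 of 11 and 6 of 10. Other large falls were MT4 (-5.22 ± 1.17), CRISP3 (-4.84 ± 1.12), FABP7 (-4.42 ± 0.88), KRT31 of the hair shaft (-4.32 ± 1.14), ANGPTL7 (-4.29 ± 1.09), PADI3 (-4.16 ± 1.29), NOS1 (-4.13 ± 0.56), PIP (-4.10 ± 1.24) and skeletal muscle actin ACTA1 (-3.97 ± 0.98). For 5 of these, 1 library held most of the nonlesional level: without the highest library the nonlesional mean went from 6.63 to 1.25 CPM for ANGPTL7, 7.01 to 2.58 for CRISP3, 10.5 to 3.48 for ACTA1, 107 to 28.3 for KRT31 and 4.53 to 0.591 for PADI3. In lesional skin the MMP1 mean went from 138 to 42.5 CPM in this way. Nonlesional means of genes that rose went from 1.03 to 0.207 CPM for CHIT1, 3.43 to 1.85 for SPP1 and 0.0705 to 0.0239 for MMP1.

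**Figure D2:**
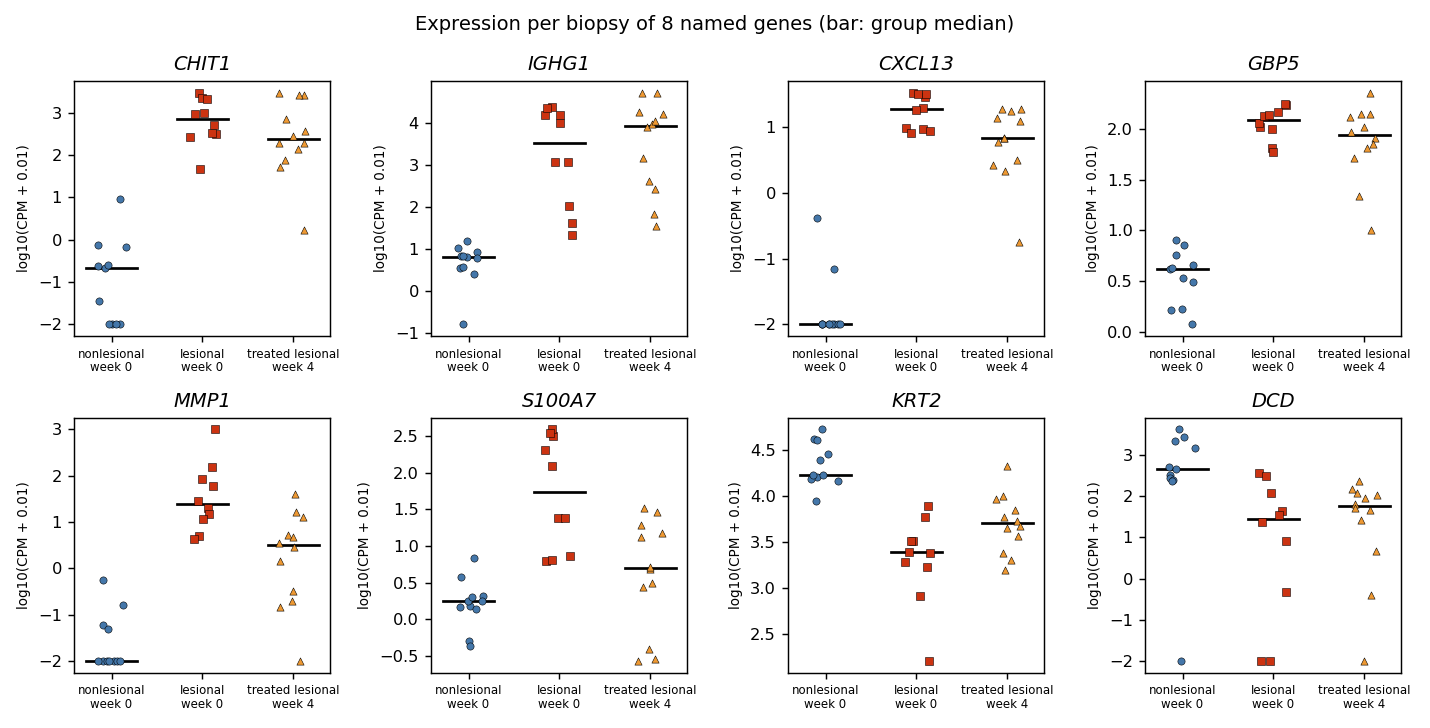
Expression of 8 named genes per biopsy, as log10(CPM + 0.01), with 1 point per biopsy and a bar at each group's median. MMP1 had a mean of 0.0705 ± 0.161 CPM in nonlesional, 138 ± 305 in lesional and 7.24 ± 11.3 in treated lesional skin (mean ± SD), and CHIT1, IGHG1, CXCL13 and GBP5 lay higher in both lesional groups than in nonlesional skin.

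Macrophage and monocyte markers rose in 25 of 25 members. They included LYZ, the lysozyme gene (97.0 ± 44.4 to 8269.8 ± 3070.4 CPM, log2 change 6.41 ± 0.60), and the integrin chain ITGAX (4.49 ± 0.42). Of granuloma and lipid-associated macrophage markers, 25 of 30 rose, among them the metalloprotease genes ADAMDEC1 (8.34 ± 0.80) and MMP9 (6.86 ± 0.75). All 13 class II presentation genes rose, including CD74, the class II invariant chain (3.55 ± 0.33), and the lysosomal protease CTSS (4.94 ± 0.44), which is also in the granuloma list. Dendritic and Langerhans cell markers rose in 17 of 23 and fell in 1, with the costimulatory receptor ligand CD86 (4.03 ± 0.36) among the rises. Complement genes rose in 14 of 21 and fell in 2. C1QA and C1QB, subunits of the first component, rose by 4.12 ± 0.48 and 4.70 ± 0.58. Adjusted over the list alone, these 5 counts were the same. The scores of the macrophage, granuloma, class II and dendritic lists differed by 1.97, 1.49, 1.89 and 1.17 (permutation test, adjusted p = 7.29e-05 for each), and that of complement by 1.02 (adjusted p = 0.000742). Score differences are in mean z, scaled per gene over all analysed biopsies, and not in SD of the score within a group.

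Lymphocyte genes rose with them. T cell markers rose in 24 of 25 members, with CD2 at 4.29 ± 0.38 and CD3D, a chain of the T cell receptor complex, at 4.56 ± 0.49. Cytotoxic and NK cell markers rose in 24 of 25. The chemokine CCL5 rose by 5.43 ± 0.58, and FGFBP2 fell by 3.79 ± 0.75. B cell and plasma cell markers rose in 28 of 30 and fell in 1, with MS4A1, the B cell antigen CD20, at 6.95 ± 0.88. Lymphoid aggregate and chemokine genes rose in 22 of 26. CXCL13, a chemokine that draws B cells to follicles, rose from 0.0421 ± 0.121 to 20.1 ± 10.7 CPM (8.67 ± 0.79). Its nonlesional mean was 0.006 CPM without the highest library, so the size of the fold leans on 1 biopsy. Of 26 listed T helper polarising genes only 13 passed the filter on counts, and 9 of these 13 rose and 2 fell. IL10, an anti-inflammatory cytokine, and FOXP3, the regulator of regulatory T cells, rose by 3.96 ± 0.60 and 3.03 ± 0.47, while GATA3, a transcription factor that lymphocytes share with other skin cells, changed by -1.64 ± 0.24. The counts adjusted over the list alone were the same for these 5 lists, and each score differed with an adjusted p of 7.29e-05 (permutation test).

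Among interferon and Janus kinase genes, JAK3, the kinase of the common gamma chain receptors (ENSG00000105639, chromosome 19, 17824780 to 17848071), rose by 3.85 ± 0.39 (adjusted p = 2.35e-09). Of the drug's targets, JAK2 (ENSG00000096968, chromosome 9, 4985033 to 5128183) rose by 0.74 ± 0.15, and JAK1 (ENSG00000162434, chromosome 1, 64833229 to 64966504) was at 0.28 ± 0.13 with an adjusted p of 0.0835 over all genes, and passed adjusted over the list alone. TYK2, STAT2, STAT3, STAT4 and STAT5A rose by 0.66, 0.43, 0.66, 2.18 and 1.20, STAT6 fell by 0.26, and STAT5B was at 0.10 ± 0.11 (adjusted p = 0.481). Interferon gamma response genes rose in 31 of 33, with the lowest p-value for the guanylate-binding protein GBP5 (4.89 ± 0.41), and type I interferon response genes in 37 of 39, with PARP9 at 2.07 ± 0.18 and PARP14 at 2.20 ± 0.18. JAK-STAT and gamma-chain cytokine components rose in 35 and fell in 2 of 42, or 37 and 2 adjusted over the list alone, with the receptor genes IL10RA (2.95 ± 0.24), IL2RG (3.93 ± 0.34) and IL7R (4.94 ± 0.43) having the lowest p-values. TNF and NF-kB response genes rose in 29 of 31, with the apoptosis inhibitor BIRC3 at 3.33 ± 0.36. The other 3 lists had the same counts adjusted over the list alone, and the 4 scores differed with an adjusted p of 7.29e-05 each (permutation test).

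The matrix changed in part. Collagen and extracellular matrix genes rose in 17 of 33 members and fell in 2. Fibronectin FN1 rose from 1148 ± 879 to 15541 ± 5138 CPM (3.76 ± 0.42), tenascin TNC by 3.07 ± 0.37 and the protease ADAM12 by 2.96 ± 0.41. By contrast, the major collagen genes COL1A2 and COL3A1 were at -0.15 ± 0.37 and -0.18 ± 0.37 (adjusted p = 0.769 and 0.71), and elastin ELN fell by 1.71 ± 0.58. Matrix-degrading proteases and inhibitors rose in 17 of 24 and fell in 1, and the protease inhibitor TIMP1 rose by 3.60 ± 0.42. Hypoxia and glycolysis genes rose in 16 and fell in 2 of 27, with the lactate exporter SLC16A3 at 6.04 ± 0.72. Cell cycle genes rose in 18 of 30, or 20 adjusted over the list alone, including the proliferation marker MKI67 (1.07 ± 0.25). The score tests gave adjusted p = 0.00353 for collagen and matrix, 7.29e-05 for proteases, 7.29e-05 for hypoxia and 0.00326 for cell cycle genes (permutation test). Of fibroblast markers, 10 rose, FAP among them (3.27 ± 0.36), and 3 fell of 23 (8 and 4 with upper-quartile scaling, where the median moved from 0.066 to -0.0034, score adjusted p = 0.269). Endothelial and pericyte markers rose in 2 and fell in 3 of 23, or 2 and 1 adjusted over the list alone, with a score difference of -0.0901 (adjusted p = 0.82). Counts for collagen, proteases, hypoxia and fibroblasts were the same adjusted over the list alone.

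Epidermal, glandular and pigment cell genes fell. Keratinocyte and cornified envelope genes fell in 19 of 29, or 20 adjusted over the list alone. KRT2, a keratin of the upper epidermis, went from 25315 ± 14216 to 2972 ± 2298 CPM (-3.09 ± 0.50), and the desmosome genes DSP and PKP1 fell by 2.06 ± 0.36 and 2.14 ± 0.32. Melanocyte genes fell in 13 of 16 and rose in 1, with DCT, an enzyme of pigment synthesis, at -2.61 ± 0.53. Eccrine sweat gland genes fell in 17 of 23 and rose in 2, or 19 and 2 adjusted over the list alone. KRT77, a keratin of sweat ducts, fell by 3.65 ± 0.49. Muscle genes fell in 12 and rose in 1 of 16 (13 and 1 adjusted over the list alone), with desmin DES at -3.82 ± 0.96. The 4 scores differed by -0.997, -1.07, -0.899 and -0.798 (permutation test, adjusted p = 0.014, 0.000197, 0.0118 and 0.0051). Stressed keratinocyte and alarmin genes went the other way, with 14 of 20 higher and 2 lower, the same adjusted over the list alone (score adjusted p = 0.00326), while limma voom called 10 of the 20. The antimicrobial S100 genes S100A7 (ENSG00000143556, chromosome 1, 153457744 to 153460701), S100A8 and S100A9 rose by 6.08 ± 0.94, 7.29 ± 0.85 and 8.48 ± 0.91. The 10 most abundant genes took 24.7 ± 7.66% of counts in nonlesional and 15.9 ± 2.42% in lesional libraries (permutation test, p = 0.00174, adjusted p = 0.00914).

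Hair follicle genes fell in 8 of 18, or 9 adjusted over the list alone, and their score did not pass (adjusted p = 0.0849). Sebaceous and epidermal lipid genes rose in 5 and fell in 12 of 22, with an edgeR median of -0.98 (score adjusted p = 0.445). Among the 5 that rose were SOAT1, which esterifies cholesterol (1.91 ± 0.27), and FAR2, which makes fatty alcohols (1.38 ± 0.32). Adipocyte genes fell in 4 of 22, or 2 adjusted over the list alone (score adjusted p = 0.312), and Schwann cell and nerve genes rose in 3 and fell in 8 of 18, or 4 and 8 adjusted over the list alone (0.175). Neutrophil and mast cell markers rose in 4 and fell in 4 of 16. Those that rose included the neutrophil receptor genes CSF3R (2.17 ± 0.22) and FPR1 (5.91 ± 0.78), and those that fell included KIT, a receptor of mast cells and melanocytes (-1.48 ± 0.29). Immediate early and heat shock genes rose in 9 and fell in 7 of 28. None of the 35 ribosomal protein, 13 mitochondrially encoded or 8 red blood cell genes passed the edgeR test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 0, 3 and 1 of them, the DESeq2 Wald test called 0, 0 and 1 and limma voom 7, 0 and 1, and the scores gave adjusted p = 0.433, 0.331 and 0.751 (permutation test). Counts for the sebaceous, neutrophil and immediate early lists were the same adjusted over the list alone, with score adjusted p = 0.283 for neutrophil and 0.283 for immediate early genes.

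**Figure D3:**
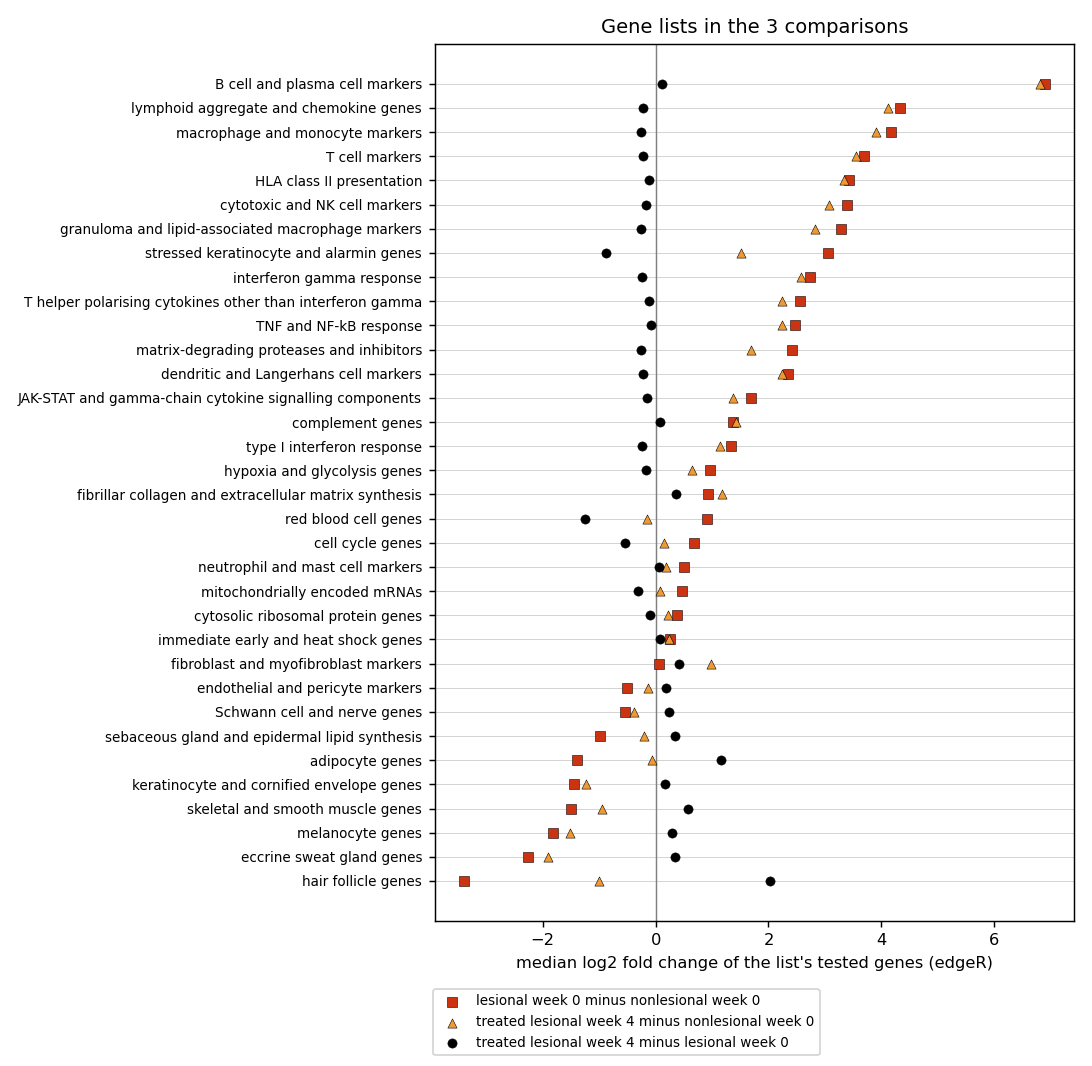
Median log2 fold change of the tested members of 34 gene lists (edgeR), with 1 marker per comparison. Macrophage markers lie at 4.16 in lesional and 3.91 in treated lesional against nonlesional skin, and at -0.25 for week 4 against week 0.

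By list score, 23 of 34 lists differed between lesional and nonlesional skin, and by fry 24. Camera with its preset correlation called 24, 19 upward and 5 downward. With an estimated correlation it called 0, and these 24 lists had adjusted p = 0.108 to 0.619.

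The second comparison asked what differed in lesional skin after 4 weeks of ruxolitinib, in a week 4 group that mixed responsive and refractory lesions. No gene passed the edgeR test: the smallest adjusted p was 0.346, and 1654 genes had an unadjusted p under 0.05 (853 higher, 801 lower) where 929 would by chance. The fit had no patient term, so changes that show only within patients can be missed. The 5 lowest p-values among named genes were those of S100A7, FABP7, MMP1, S100A8 and SERPINB4. S100A7 was at 146 ± 158 CPM at week 0 and 10.6 ± 11.6 CPM at week 4 (log2 difference -3.78 ± 0.81, unadjusted p = 5.08e-05, lower than the week 0 median in 12 of 12 biopsies). MMP1 was at 138 ± 305 and 7.24 ± 11.3 CPM (-4.25 ± 0.99, unadjusted p = 0.000147, lower in 11 of 12), and SERPINB4, a serine protease inhibitor of stressed keratinocytes, at 58.8 ± 78.6 and 2.66 ± 3.73 CPM (-4.45 ± 1.08, unadjusted p = 0.00024). FABP7, a fatty acid binding protein, was higher at week 4 in 12 of 12 biopsies, at 0.553 ± 0.672 against 7.37 ± 12.4 CPM (3.70 ± 0.84, unadjusted p = 0.000112). Of the other tools, limma voom and limma-trend on FPKM called 0 genes, and the DESeq2 Wald test called 25, 16 that rose and 9 that fell. Those 9 included S100A7 (log2 change -3.76, adjusted p = 0.00257), S100A8 (-2.76, 0.0217) and the stromelysin MMP3 (-3.51, 0.0435), and FABP7 (3.76, 0.00257) was among those that rose. Some means leaned on 1 library. Without the highest library, week 0 means went from 138 to 42.5 CPM for MMP1, 52.2 to 22.6 for MMP3 and 0.553 to 0.364 for FABP7. Week 4 means went from 7.24 to 4.34 CPM for MMP1 and 7.37 to 4.27 for FABP7.

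Cell cycle genes had the clearest list difference at week 4. Of 30 members, 29 had a negative log2 difference with a median of -0.55, 0 passed over all genes in edgeR, DESeq2 or limma voom, 15 had an unadjusted p under 0.05 in edgeR, and 11 fell adjusted over the list alone. MKI67 was at 157 ± 52.1 and 89.5 ± 28.5 CPM (-0.81 ± 0.24, unadjusted p = 0.00215), and the mitotic kinase AURKA at 7.70 ± 2.28 and 3.87 ± 1.45 CPM (-0.99 ± 0.31, lower in 12 of 12 biopsies). The score fell by 0.743 (permutation test, adjusted p = 0.0121), fry gave adjusted p = 0.0222, and camera adjusted p = 0.125 with an estimated correlation. Each was adjusted over the 102 tests, which include the comparisons with nonlesional skin. Fry was not adjusted over this comparison alone. Of 100 splits of these biopsies, the real one included, 46 gave at least 1 list by fry. Adjusted over the 34 lists of this comparison alone the score p was 0.162, and with all 36 libraries it was 0.108 over the 102 tests.

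**Figure D4:**
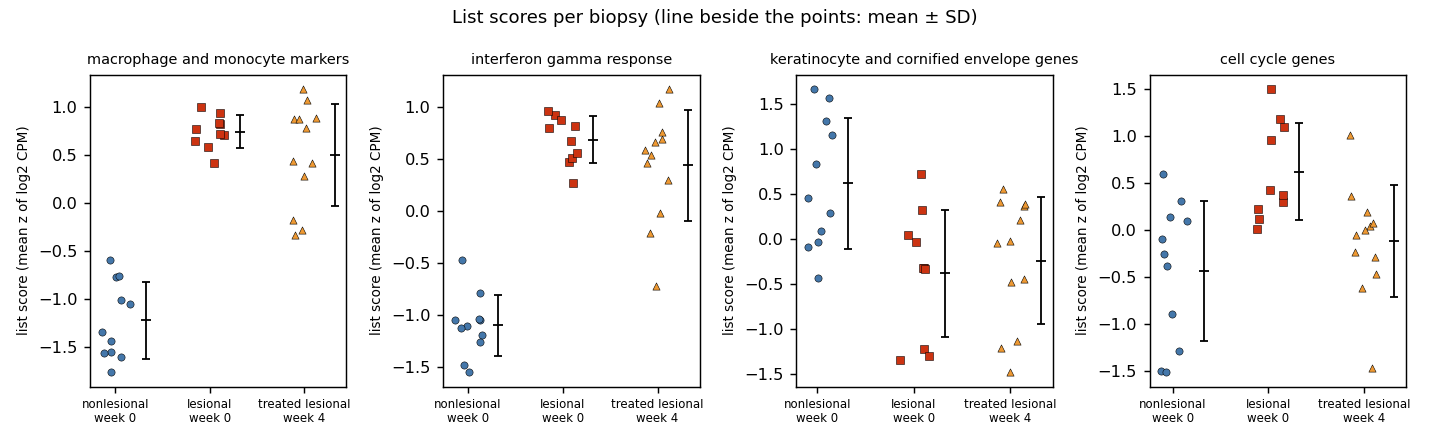
Scores of 4 gene lists per biopsy (mean z-scored log2 CPM), with 1 point per biopsy and the group mean ± SD beside the points. The cell cycle score was lower at week 4 than at week 0 in lesional skin by a mean difference of -0.743, and the macrophage difference was -0.242.

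For the genes nearest to the drug's action, none of the week 4 differences given here passed. Biopsies differed, in a look taken after the result was seen: 3 of 12 treated biopsies had an interferon gamma score below that of every lesional biopsy at week 0, and the other 9 had a mean of 0.689 against 0.684 at week 0. Leaving out the lowest scores raises a mean by construction. For macrophage scores 4 of 12 were below every lesional biopsy, the same 3 among them, and for granuloma scores 5, with 2 of the 3 among them. The 9 biopsies other than these 3 had a macrophage mean of 0.758 against 0.745. STAT3 was at -0.34 ± 0.12 (adjusted p = 0.486), PARP9 at -0.53 ± 0.17 (0.426) and the guanylate-binding protein GBP2 at -0.46 ± 0.16 (0.486). JAK1, JAK2, JAK3 and TYK2 were at -0.15 ± 0.13, -0.27 ± 0.15, -0.28 ± 0.34 and 0.12 ± 0.24 (adjusted p = 0.77, 0.599, 0.862 and 0.926). Negative differences were found in 28 of 33 interferon gamma response, 31 of 39 type I interferon response and 33 of 42 JAK-STAT genes, with medians of -0.24, -0.24 and -0.16. In edgeR 0 members of the 3 lists passed, over all genes or adjusted over the list alone, with 2, 4 and 5 at an unadjusted p under 0.05 and 0 by DESeq2 or limma voom. The score tests gave adjusted p = 0.29, 0.164 and 0.181 (permutation test).

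Among the other lists, 4 of 20 alarmin genes and 2 of 24 proteases fell adjusted over the list alone, eccrine genes had 1 that rose and 1 that fell, and 0 members of each passed over all genes in edgeR. At an unadjusted p under 0.05 there were 6, 2 and 2 such genes, and DESeq2 called 2, 1 and 0 and limma voom 0. The alarmin median was -0.88 and the score adjusted p 0.192. Median differences were -0.25 for macrophage, -0.26 for granuloma, -0.23 for T cell and -0.23 for lymphoid aggregate genes (score adjusted p = 0.283, 0.224, 0.4 and 0.136). CXCL13 was at 20.1 ± 10.7 and 9.04 ± 6.83 CPM (-1.15 ± 0.51, adjusted p = 0.528), lower than the week 0 median in 12 of 12 biopsies. Positive differences were found in 28 of 33 collagen and matrix genes (median 0.35, score adjusted p = 0.129), with COL1A2 at 12831 ± 5002 and 28030.0 ± 18459 CPM (1.13 ± 0.37, adjusted p = 0.459, 19000.0 ± 5743 CPM in the 9 biopsies without the 3 of low interferon gamma score, which had the 3 highest values) and COL3A1 at 1.07 ± 0.37 (0.486). All 18 hair follicle genes had positive differences (median 2.03, score adjusted p = 0.276). Camera with its preset correlation called 21 lists, 5 upward and 16 downward, and 0 with an estimated correlation (adjusted p = 0.125 to 0.679 for these 21), while fry and the score test called 1, the cell cycle list. With all 36 libraries camera called 9 and the score test 0. The 10 most abundant genes took 20.2 ± 3.93% of counts at week 4 and 15.9 ± 2.42% at week 0 (permutation test, p = 0.0069, adjusted p = 0.029).

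Signs differed among readouts for some lists. At week 4 against week 0 the median and mean on log2 CPM and the score difference were -0.044, 0.04 and -0.00257 for B cell, 0.10, -0.056 and 0.0486 for neutrophil, and 0.097, 0.033 and -0.0152 for immediate early genes, and the edgeR median for B cell genes was 0.11. For complement genes the edgeR median was 0.081 and the mean on log2 CPM -0.015. For treated lesional against nonlesional skin the median and mean on log2 CPM were 0.14 and -0.068 for hair follicle genes, where the edgeR median was -1.01, -0.12 and 0.11 for sebaceous genes and 0.017 and -0.027 for mitochondrial mRNAs.

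The share of the lesional change reversed at week 4 was 9.78% (SD 3.32 over 20 halvings, range 4.33% to 16.9%) over a mean of 4304 genes changed at least 2-fold. It was 3.88% for genes that were higher in lesional skin and 22.7% for genes that were lower, and this difference was not tested. The 2 shares were -1.51% and 10.7% with all 36 libraries and 9.43% and 28.4% without the 3 low-complexity libraries. A quick form of the share was 12.7%, and exchanging week 0 and week 4 labels gave a quick share as far from 0 in 28 of 100 draws, the real labels included (p = 0.28). For the genes that were higher and lower it was 10.7% and 17.4% (p = 0.31 and 0.28, adjusted p = 0.31 for each). The real quick shares were means over 20 halvings, while each exchange used 1 halving, which varies more. These p-values can therefore be too large, and the test cannot decide whether the share differs from 0. The share was 1.43% with all 36 libraries and 15.5% without the 3 low-complexity libraries, 1 of lesional and 2 of treated lesional skin.

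The third comparison asked how lesional skin after 4 weeks of therapy differed from nonlesional skin. IGHM and IGHG1 rose by 12.21 ± 1.83 and 11.08 ± 1.47, though the treated IGHM mean went from 3360.0 to 903 CPM without its highest library. CHIT1 was at 866 ± 1174 CPM against 1.03 ± 2.76 (9.75 ± 1.38, adjusted p = 1.54e-06). The sweat gland genes DCD, which encodes an antimicrobial peptide (ENSG00000161634, chromosome 12, 54644591 to 54648493), and PIP fell by 3.94 ± 1.20 and 4.48 ± 1.17, and WDR72, MUC7 and WIF1 were at -3.80 ± 0.53, -3.50 ± 1.12 and -4.29 ± 0.74. Without its highest library the nonlesional MUC7 mean went from 6.64 to 2.75 CPM. IGHG3 and IGHG4 rose by 10.38 ± 1.66 and 10.03 ± 1.76. In all, 7480 genes changed, 4052 upward and 3428 downward, and 2578 and 1339 at least 2-fold. With limma-trend on log2(FPKM + 1) the split was 3265 upward and 4384 downward.

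Immune lists other than neutrophil and mast cell markers were higher in treated lesional than in nonlesional skin. Those markers rose in 4 and fell in 3 of 16 (permutation test of the score, adjusted p = 0.196). Macrophage markers rose in 25 of 25, T cell markers in 24 of 25, class II genes in 13 of 13, interferon gamma response genes in 31 of 33, and TNF and NF-kB genes in 27 of 31, the same adjusted over the list alone. Collagen and matrix genes rose in 29 of 33, fibroblast markers rose in 10 and fell in 1 of 23, and both scores differed (adjusted p = 0.000106 and 0.0181). COL1A2 was at 0.98 ± 0.36 (adjusted p = 0.0295). Keratinocyte genes fell in 13 of 29 (17 adjusted over the list alone), melanocyte genes in 13 of 16 (14) and eccrine genes in 15 of 23 (16). Alarmin genes rose in 7 and fell in 2 of 20 (limma voom called 5), with a score adjusted p of 0.0673, and S100A7 was at 2.30 ± 0.78 (adjusted p = 0.0192). Cell cycle genes rose in 2 and fell in 1 of 30 (1 and 1 adjusted over the list alone), with a score adjusted p of 0.373. By score 20 lists differed, by fry 23, and by camera 22 with the preset correlation and 0 with an estimated one (adjusted p = 0.108 to 0.6 for these 22).

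The first and the third comparison share the nonlesional libraries. Of the genes that rose in lesional skin, 3634 also rose in treated lesional skin, against 969 for independent lists of these sizes, and of those that fell 2899 also fell, against 775. No gene changed in opposite directions. Simulated unchanged groups against the same libraries shared 0 genes, with calls by limma-trend on log2 CPM and not by edgeR. Unchanged groups give few calls at this threshold, so this 0 does not measure what the shared libraries add to the overlap. With the nonlesional libraries split between the comparisons, 2518 and 2537 genes rose in both, 1585 and 1642 fell in both, and 1 and 11 changed in opposite directions. The covariance of the fold changes across genes, which are not independent replicates, was 1.62, against 0.064 simulated and 1.51 with split libraries (r = 0.964, 0.455 and 0.859). Between the first and second comparisons, which share the lesional libraries, it was -0.253, against -0.072 simulated and -0.2 with split libraries (r = -0.494, -0.511 and -0.341).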

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

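The rule for a library far from the others was set before the data were seen, and the genes it ran on and the check of the left-out libraries were chosen only after. In lesional skin at week 0 (n = 10), 5 of 128 values tested had 1 library whose gap to its nearest neighbour was a large share of the group's range. The share was 0.688 for the number of genes with 1 count and 0.647 for log2 CPM of ELN, each from the lowest library. It was 0.651 for the mitochondrial share of counts, 0.469 for log2 CPM of CD3D and 0.518 for log2 CPM of FOXP3, each from the highest. Chance alone gives such a gap in about 1 in 20 groups, which is more than were found here.

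Among the 3 libraries that the labels mark as left out of the differential analysis, 2 had a macrophage score above -0.594, the highest score of the 11 analysed nonlesional libraries. The lowest scores of the analysed lesional and treated lesional libraries were 0.423 and -0.326. The left-out libraries were 1 nonlesional and 2 lesional ones, so 2 scores above the nonlesional range need not be unusual. Immunoglobulin genes took 0.926% of counts in the left-out nonlesional library, against at most 0.0258% in the 11 analysed ones. In the left-out lesional libraries they took 0.105% and 0.0383%, within the range of the analysed lesional ones (0.0289% to 12.2%). The cause of these values was not tested.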

How the results depend on the processing

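The tests without the low-complexity libraries, with protein-coding genes alone and with scores adjusted within a comparison were chosen only after the results were seen. No paired analysis was run because the labels give no number that ties biopsies of different groups to a patient. Lesional against nonlesional skin gave 7344 to 10026 changed genes under the other tools and settings and treated lesional against nonlesional skin 6281 to 8590, and a 2-fold minimum left 4885 and 3917, since it removes smaller changes. For week 4 against week 0 in lesional skin the DESeq2 Wald test called 25 genes against 0, and the cause was not tested. With an estimated correlation camera called 0 lists in each of the 3 comparisons, since that correlation (0.0816 to 0.859) replaced 0.01. For week 4 against week 0, fry called 1 list and camera with all 36 libraries 9, and the score test called 0 with all 36 libraries and 0 adjusted within the comparison, where 34 tests share the adjustment. For fry and the 36-library values the cause was not tested. The reversed share was 9.78%, 1.43% with all 36 libraries, 15.5% without the low-complexity libraries and 14.0% with no halving, where shared libraries add to it, and the cause of the first 2 differences was not tested. The sign of the log2 value turned for 26 list means and 59 gene values. In 4 of them, all week 4 list means, 1 of the 2 fits passed: TNF and NF-kB response, T cell and class II with all 36 libraries, and ribosomal protein genes with the covariate. In the others neither fit passed. With all 36 libraries the values were, in week 4 against week 0 for TNF and NF-kB response 0.010, T cell 0.11, cytotoxic and NK cell 0.12, HLA class II presentation 0.028, neutrophil and mast cell 0.051, endothelial and pericyte -0.14, adipocyte genes -0.48, melanocyte genes -0.13, complement genes 0.15, C1QA 0.021, CCL5 0.15, CD74 0.12, DCT -0.40, DSP -0.081, FOXP3 0.14, IGLC7 0.041, IL10RA 0.047, NOS1 -0.30, SLC16A3 0.086, SPP1 0.063, STAT5A 0.013, and in lesional against nonlesional skin for endothelial and pericyte 0.037, COL1A2 0.35, COL3A1 0.38. With log10 total count as covariate the values were, in week 4 against week 0 for B cell and plasma cell -0.23, neutrophil and mast cell 0.014, endothelial and pericyte -0.0063, complement genes 0.0073, cytosolic ribosomal protein genes 0.15, ADAM12 -0.098, STAT5B -0.0048, TYK2 -0.11, and in lesional against nonlesional skin for endothelial and pericyte 0.019, cytosolic ribosomal protein genes -0.22, and in treated lesional against nonlesional skin for endothelial and pericyte 0.013, sebaceous gland and epidermal lipid synthesis -0.062, cytosolic ribosomal protein genes -0.073. With the low-complexity libraries left out the values were, in week 4 against week 0 for B cell and plasma cell -0.38, adipocyte genes -0.12, ADAM12 -0.17, C1QB -0.27, IGHG1 -0.47, IGHG3 -0.036, IGHG4 -0.28, IGHM -1.46, IL10 -0.059, MUC7 0.18, and in treated lesional against nonlesional skin for endothelial and pericyte 0.15, hair follicle genes 0.38, mitochondrially encoded mRNAs 0.19, ELN 0.041. With DESeq2 size factors the values were, in week 4 against week 0 for complement genes 0.012. With limma voom the values were, in week 4 against week 0 for ADAM12 -0.0028, C1QB -0.36, DCD 2.13, IGHG1 -0.51, IGHG3 -0.81, IGHG4 -0.14, IGHM -0.87, IL10 -0.18, MUC7 1.98, PIP 0.66, STAT5B -0.016, TYK2 -0.0091, and in lesional against nonlesional skin for COL1A2 0.30, COL3A1 0.25. With no filter on low counts the values were, in week 4 against week 0 for ADAM12 -0.0057. With limma-trend on log2(FPKM + 0.1) the values were, in week 4 against week 0 for ADAM12 -0.046, C1QB -0.41, DCD 1.09, DSP -0.038, IL10 -0.12, PIP 0.28, and in lesional against nonlesional skin for COL1A2 0.042, COL3A1 0.067. With limma-trend on log2(FPKM + 1) the values were, in week 4 against week 0 for ADAM12 -0.033, C1QB -0.40, DCD 0.71, DSP -0.037, IL10 -0.0077, PIP 0.074, and in lesional against nonlesional skin for COL1A2 0.042, COL3A1 0.067. With the DESeq2 Wald test the values were, in week 4 against week 0 for IGHM -1.26, and in treated lesional against nonlesional skin for PADI3 0.83. Fibroblast markers in lesional against nonlesional skin had a median of 0.066, and of -0.0034 with upper-quartile scaling. The cause of these turns was not tested. A named gene lost its call 24 times in lesional and 47 times in treated lesional against nonlesional skin, 5 and 10 of them with limma voom and 5 and 10 with limma-trend on log2(FPKM + 0.1). With limma-trend on log2(FPKM + 0.1) the median log2 change of all genes in treated lesional against nonlesional skin was -0.10 against -0.024. The recovered share of simulated 1.5-fold changes was 26.4% for week 4 against week 0.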

Other observations

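The gene families, the splits, and the tests of 3 patterns reported here were chosen only after the results were seen. Families of genes with related symbols, some of whose members are in the fixed lists, were counted in lesional against nonlesional skin, where 4446 of all 18589 genes rose and 4203 fell. No family was tested against other genes. All 10 tested leukocyte immunoglobulin-like receptor genes rose (median log2 fold change 3.38), as did 5 of 5 SLAM family receptors (4.93), 9 of 11 toll-like receptors (2.54), 8 of 11 sialic acid-binding lectins (2.92), 9 of 10 TNF superfamily ligands and 5 of 7 Fc receptor-like genes (5.12). Of 20 TNF receptor superfamily genes 17 rose and 3 fell, and of 31 integrins 10 rose and 7 fell, with a median of -0.12 over all members. Of 14 cathepsins, the lysosomal proteases, 11 rose and 1 fell, and 6 of the 14 are in fixed lists. In each of these families rises also outnumbered falls with DESeq2 size factors and upper-quartile scaling.

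In the other direction, 18 of 39 cytochrome P450 genes fell and 6 rose and 11 of 25 aldehyde and alcohol dehydrogenase genes fell and 3 rose. Of 28 tested HOX genes, which set position along the body axis, 10 fell and 0 rose. Of 13 connexins, the subunits of gap junctions, 6 fell and 1 rose. Falls outnumbered rises in these families under both other scalings too.

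Among 100 drawn splits of the biopsies, the real one included, 1 gave as many changed genes as lesional against nonlesional skin (8649 against 3882 for the highest other), and 1 as many as treated lesional against nonlesional skin (7480 against 1804). Only the real split reached either count. The splits treat biopsies as independent, and 100 of them make chance unlikely for both counts without excluding it. For week 4 against week 0 the real count was 0, which all 100 splits reached, and the highest other was 109. For genes at an unadjusted p under 0.05, 8 of 100 splits reached the real 1654, with a median of 547 and a highest of 3441 among the others. Camera with the preset correlation called 24, 21 and 22 lists in the 3 comparisons, in the order of the report, and 11, 25 and 29 of 100 splits called as many (highest other 28, 27 and 26). Chance is not excluded for these counts. Fry called 24, 1 and 23, which 1, 46 and 1 splits reached (highest other 18, 11 and 19), so chance is unlikely for the comparisons with nonlesional skin alone. A quick form of the reversed share was 12.7%, and 28 of 100 exchanges of labels lay as far from 0, the farthest at 31.5%.

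The first pattern was the lower level of keratinocyte, melanocyte and eccrine gland genes in lesional skin, by 3 mean log2 CPM differences of -1.36, -1.57 and -2.07. Dilution of all resident tissue by infiltrating cells would lower other resident cells alike, but endothelial markers differed by -0.059 and fibroblast markers by 0.63. Their edgeR medians were -0.51 and 0.066. Muscle, adipocyte and hair follicle lists had mean log2 CPM differences of -1.20, -0.78 and -1.18 and edgeR medians of -1.50, -1.39 and -3.40, which go with dilution. The 3 lists fell by 1.61 more than the endothelial list (permutation test, p = 0.00044) and by 2.30 more than the fibroblast list (p = 4e-05). Of fibroblast markers 10 of 23 rose and of endothelial markers 2 of 23, and such rises can hide dilution. The differences argue against dilution as the whole cause only if these 2 lists are not raised within lesional cells. With log10 total count as covariate at least 87.2% of the change of each of the 3 lists was left, which argues against library size. A lower epidermal and glandular share of the tissue, or lower expression in these cells, may remain as a hypothesis, and a different depth or site of the biopsies was not tested.

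The second pattern was the lower cell cycle score at week 4 in lesional skin, at -0.12 ± 0.596 against 0.623 ± 0.519 (mean ± SD, n = 12 and 10). The difference was -0.729 without the 3 low-complexity libraries (permutation test, p = 0.0111), which argues against these libraries as the whole cause. Chance stays open, since adjusted over the 34 lists of this comparison the p was 0.162. Fewer infiltrating immune cells also stay open: the mean macrophage, T cell and B cell score differed by -0.143 (p = 0.372), and the cell cycle score less that mean by -0.600 (p = 0.0395, adjusted p = 0.0593 over 3 measures). A lower rate of cell division during therapy may be a hypothesis for other biopsies, and no group without the drug was measured.

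The third pattern was the spread of plasma cell genes among lesional biopsies, where immunoglobulin genes took 0.0289% to 12.2% of counts at week 0 and 0.0335% to 20.1% at week 4. A trade-off between plasma cells and granuloma macrophages could give a negative correlation of their scores. Pearson's r was -0.367 at week 0 (permutation p = 0.291, adjusted 0.487, n = 10), rho was -0.248 (p = 0.492), and r without the 2 farthest biopsies was -0.418. At week 4 r was 0.117 (p = 0.713) and rho 0.0909 (p = 0.783, n = 12), with r = -0.133 without 2. The total count correlated with the plasma cell score at r = -0.429 at week 4 (p = 0.164, rho = -0.28, p = 0.379, r = -0.513 without 2) and -0.357 at week 0 (p = 0.325, rho = -0.152, p = 0.683, r = -0.259 without 2). These were 4 of 6 relations computed, and with 10 and 12 biopsies neither explanation can be excluded.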
